A study of Homo sapiens with 44 samples.

How the data were processed

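The 44 samples come from CT30, an established line of human trophoblast stem cells, per the labels. Of these, 15 are 3′ RNA sequencing libraries (QuantSeq, which reads near the 3′ end of transcripts) and 29 are chromatin immunoprecipitation (ChIP) or input samples. The knockdown table holds 3 libraries with a short hairpin RNA against GFP (shGFP, the control), 3 with a first hairpin against MSX2 (KD1) and 1 with a second hairpin (the library labelled KD2). All 7 were self-renewing (SR) cells given lentivirus for 16 h, read at 50 bp. The inducible table holds cells that carry an MSX2 coding sequence under doxycycline control, read at 100 bp. It has 3 SR libraries without doxycycline, 3 libraries of syncytiotrophoblast (ST) differentiation with 2 µM forskolin and no doxycycline, and 2 of ST differentiation with forskolin and 1 µg/ml doxycycline (replicates 2 and 3).

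The deposited gene tables hold counts, whole raw read counts for each of 42943 genes, with no normalization. Per the submitters' processing notes, Trim Galore 0.6.5, cutadapt 2.8, STAR 2.7.3a and SAMtools 1.10 were used on build hg38 for RNA, and Trim Galore, cutadapt, Bowtie2 2.3.5.1, SAMtools, MACS2 2.2.7.1 and deepTools 3.5.0 for ChIP. Their roles and order are not given in the sources used here, nor are the counting program and its use of strand. Each gene is a single interval that includes introns, so overlapping or antisense genes and near-identical families (CGB, PSG, CSH) carry uncertain counts. The deposited peak lists hold other values, chromosome, start and end alone, with no score, height or p per peak. Their names say that they were made over replicates with a reproducibility measure (IDR) whose threshold is not stated. There is 1 list each for MSX2 in untransduced cells and for ARID1A, SMARCA4, H3K27ac, H3K27me3 and H3K9me3 in untransduced cells and in transduced MSX2 knockdown cells. The 6 input samples have no processed file and were not analysed here, and the depth of the ChIP libraries is unknown. Peak starts are printed counted from 1.

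Library totals ran from 10110497 to 20600046 counts in the knockdown table and from 4294127 to 9163404 in the inducible table. With edgeR 4.0.16 and limma 3.58.1 in R 4.3.3, genes were kept by filterByExpr (15075 and 13087 genes), normalized by TMM (factors 0.945 to 1.08 and 0.670 to 1.25) and tested with the quasi-likelihood test, 1 fit per table over all of its libraries and groups. The common biological coefficient of variation was 0.220 and 0.344, with 4 and 5 residual degrees of freedom. A gene was called when its Benjamini-Hochberg adjusted p was below 0.05. All tests were two-sided, and the p-values of the gene tests measure only the spread between these samples. The p-values of the list tests by camera with a preset correlation, described below, rest on the spread across genes. They do not measure the spread between samples. Those of Fisher's exact test treat genes as independent, which they are not, and do not measure the spread between samples. The library labelled KD2 is the only one of its group, so it was assumed to vary like the other groups. Levels are CPM, counts scaled to a common library size after TMM normalization, given as mean ± SD. Log2 fold changes carry a standard error (SE) derived from the test, the absolute log2 fold change over the square root of its F value. Counting intervals, at 95%, and floors cover counting error only. Where a group had no count of a gene, the fold was bounded against a floor of 3 counts over the group. Where it had 1 to 3 counts, the ratio is given with its counting interval. Every pair of replicates differed by more than sampling noise (chi-square over degrees of freedom 6.37 to 180.4).

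Comparisons, tests, gene lists and the rule for named genes were fixed before the data were examined. The rule took MSX2 first. It then took, per comparison, the 10 largest rises and the 10 largest falls among called genes with a mean log2 CPM of at least 1, a symbol and no overlap between the libraries of the groups. For 3 libraries against 3, chance alone separates 10% of genes. It also took up to 4 called members per list with the largest change (or the 2 with the highest mean if none was called), up to 10 genes bound by MSX2 that rose on KD1 and fell with doxycycline, and up to 5 in the reverse direction. The 5 MSX2 peaks with the highest score, also in the rule, could not be taken because the lists hold no score. The text draws its examples from these genes, mostly from those whose calls were kept when any 1 library was left out. This held for 57 of 74 called named genes for KD1, 32 of 48 for the library labelled KD2, 74 of 83 for differentiation, 30 of 88 for doxycycline in ST cells, 35 of 69 for ST cells with doxycycline against SR and 12 of 28 for the difference between hairpins.

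The 18 lists were ST hormones and steroidogenesis, the PSG family, cell fusion and ST regulators, trophoblast stem and cytotrophoblast, extravillous trophoblast, proliferation, SWI/SNF subunits, BMP targets and MSX/DLX homeobox genes, interferon response, p53 targets, hypoxia and glycolysis, cholesterol synthesis, cAMP immediate response, mesenchymal stroma, amnion, endothelium and immune cells, mitochondrially encoded genes (as a sign of RNA quality), and keratins and squamous epithelium. The mitochondrially encoded genes and loricrin were matched under the symbols the tables use. Each list was tested against the other genes with camera on voom values with a preset correlation of 0.01 between genes, adjusted over 108 tests. Camera with an estimated correlation was run beside it, and fry, which tests whether a list moves on balance 1 way and does not compare it with other genes. Of the 108 tests, 46 were called, 2 with the estimated correlation (ST hormones for KD1 and for the library labelled KD2) and 40 with fry. With the preset correlation camera takes its degrees of freedom from the number of genes, with an estimated one from the few residual ones. The camera settings thus differ in more than the correlation. For ST hormones on KD1 the estimated correlation was 0.00752, below the preset 0.01, while the unadjusted camera p went from 1.58e-22 to 5.64e-04.

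Call sets of the 2 tables, which share no library, were compared by Fisher's exact test on 12635 genes tested in both. Comparisons that share control libraries were set beside 50 simulations of each table with no effect. These drew noise independently for each gene, with no correlation between genes and no effect of replicate number. Peak work used GenomicRanges 1.54.1. A gene counted as bound with a peak within 5 kb of its annotated start, and a peak as shared with an overlap of at least 1 bp. MSX2 peaks were shuffled 100 times within their chromosomes, to any position and without matching to regulatory regions. Genes are not independent replicates, so correlations across genes carry no p.

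Replicate numbers were checked for pairing by correlating residuals between groups, with a minimum of 0.1. For shGFP and KD1 the same numbers gave 0.286, 0.111 and 0.148, so fits with replicate number as a block are given beside KD1. Different numbers gave -0.242 to 0.149, so the pairing is not certain. For SR and ST without doxycycline they gave 0.151, -0.006 and 0.203, and this table was treated as unpaired. For ST without and with doxycycline they gave 0.195 and 0.460, and with the block 2426 genes changed with doxycycline. Here ST without doxycycline replicate 1 and ST with doxycycline replicate 2 gave 0.335. With only 2 doxycycline libraries the residuals of 1 mirror those of the other, so these values are not independent. The code was tested on simulated data with 200 changed genes. For KD1, 6.2% of genes changed 1.5-fold, 43.8% changed 2-fold and 80% changed 4-fold were recovered, with 4 false calls. For the library labelled KD2 the shares were 1.5%, 12.1% and 56.1%, for differentiation 0%, 1.6% and 57.6%, and for doxycycline 0%, 0% and 24.1%. A planted list was recovered in each, and 1 other list was falsely called, for KD1.

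The alternatives were size factors by DESeq2's method inside edgeR, the DESeq2 1.42.0 test, no filter or a filter of 1 CPM in 2 libraries, a 2-fold minimum, an adjusted p below 0.01 for overlaps, fits of only the groups compared, replicate blocks, both hairpins as 1 group and leaving out each library. For peaks they were windows of 1 kb and 50 kb, other overlap rules and a background matched on expression. A fit without the mitochondrial genome's counts, and blocks in the fits of single libraries, were added after seeing the data. The size factors moved the median log2 fold change of all genes by -0.03 to 0.02.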

Results

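Gene expression and chromatin were profiled in human trophoblast stem cells (hTSC), cells of the placental epithelium that self-renew (SR) or, with the cAMP agonist forskolin, form syncytiotrophoblast (ST), the fused hormone-secreting layer of the placenta. The question the labels pose is what the homeobox transcription factor MSX2 does in these cells and how it relates to the SWI/SNF chromatin remodelling complex, of which ARID1A and SMARCA4 are subunits. RNA was measured in 7 libraries of SR cells with hairpin RNAs (3 shGFP control, 3 KD1, 1 labelled KD2), with 10110497 to 20600046 counts each. A further 8 libraries came from cells with doxycycline-inducible MSX2 (3 SR and 3 ST without doxycycline, 2 ST with doxycycline), with 4294127 to 9163404 counts each. ChIP peak lists covered MSX2 (3 samples), and ARID1A, SMARCA4 and the histone marks H3K27ac, H3K27me3 and H3K9me3 (2 samples each in untransduced and 2 each in MSX2 knockdown cells).

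MSX2 itself (chromosome 5, 174724582 to 174730896, plus strand, hg38) was measured at 139 ± 26.7 CPM in shGFP cells (n = 3) and fell on KD1 to 92.5 ± 11.4 CPM (n = 3; log2 fold change -0.59, SE 0.16, adjusted p = 0.0474). This call was lost without shGFP replicate 1 (adjusted p = 0.126), replicate 2 (0.111) or replicate 3 (0.0562) and without KD1 replicate 2 (0.165) or replicate 3 (0.160), and with replicate number as a block it was -0.58 (adjusted p = 0.00621). In the library labelled KD2, MSX2 stood at 141 CPM, a log2 fold change of 0.03 from shGFP (adjusted p = 0.967; -0.21 and 0.464 with the block), and with both hairpins as 1 group the change was -0.41 (adjusted p = 0.264). The tested difference between KD2 and KD1 at MSX2 was 0.61 on the log2 scale (adjusted p = 0.225). On ST differentiation without doxycycline MSX2 fell from 211 ± 27.9 to 112 ± 37.3 CPM (log2 fold change -0.92, SE 0.29, adjusted p = 0.0308, n = 3 and 3). That call was lost without SR replicate 1 (0.0949), 2 (0.0603) or 3 (0.0656) or ST replicate 2 (0.0585). With doxycycline MSX2 rose to 253 ± 29.2 CPM in ST cells (n = 2; log2 fold change 1.18 against ST without, SE 0.31, adjusted p = 0.0346). This call was lost without SR replicate 1 (0.0536), 2 (0.0640) or 3 (0.0611), ST without doxycycline replicate 2 (0.0773), ST with doxycycline replicate 2 (0.175) or 3 (0.136), and in a fit of only these groups (0.109). Against SR cells, ST cells with doxycycline differed by 0.26 (adjusted p = 0.616). The induced construct holds the coding sequence, so counts near the 3′ end of the native transcript need not measure all of it.

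**Figure D1:**
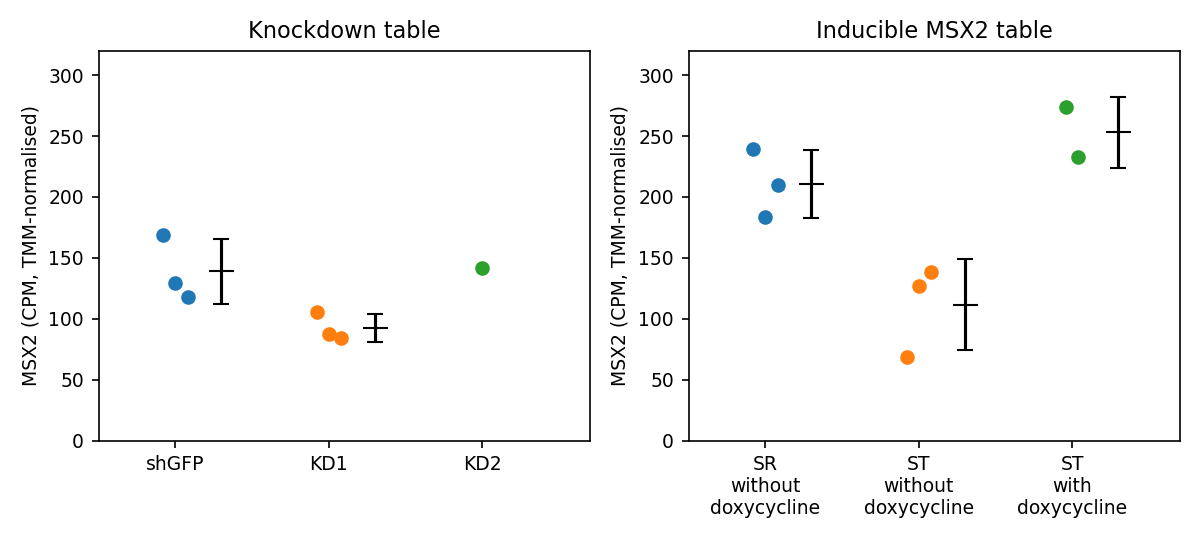
MSX2 level in each RNA library, in CPM on a linear axis from 0; points are libraries and bars are group means with SD. KD1 libraries lie at 84.1 to 105 CPM, below the shGFP libraries at 118 to 169 CPM, and the library labelled KD2 lies at 141 CPM.

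On MSX2 knockdown with the first hairpin, hormone genes of the ST rose while cells were held in self-renewal. LGALS13, which encodes a placental galectin, rose from 0.633 ± 0.184 to 27.5 ± 2.32 CPM (43.4-fold, log2 SE 0.27), and LEP, the hormone leptin, from 0.280 ± 0.196 to 12.0 ± 5.20 CPM (40.5-fold, SE 0.52; n = 3 and 3 here and below). CGA, the shared alpha subunit of chorionic gonadotropin, rose from 976 ± 149 to 11870 ± 427 CPM (12.2-fold, SE 0.14); it was named after its values were seen. Among the largest falls were INHBA, the activin A subunit, from 27.1 ± 7.37 to 1.52 ± 0.148 CPM (log2 fold change -4.14, SE 0.28). COL17A1, a collagen that anchors basal epithelial cells, fell from 121 ± 8.54 to 14.3 ± 3.68 CPM (-3.08, SE 0.19) and ANKRD1, a known YAP target, from 71.3 ± 13.7 to 8.10 ± 3.59 CPM (-3.11, SE 0.28). Other large rises were PSCA (6.53, SE 0.50), GPR78 (5.71), TPPP3 (5.51) and CRYAB, a small heat shock protein (5.03). Other large falls were SPP1, or osteopontin (-4.10), PTGS2, the prostaglandin synthase (-3.93), and complement C3 (-3.56). In all, 1330 of 15075 genes changed by the edgeR test, 920 up and 410 down, 667 of them at least 2-fold. The count was 702 without shGFP replicate 2, 710 without shGFP replicate 3, 2223 without KD1 replicate 1, 798 without KD1 replicate 2 and 839 without KD1 replicate 3. With replicate number as a block it was 2246, including 1327 of the 1330.

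Of 21 measured genes for ST hormones and steroidogenesis, 20 rose on KD1 and 1, INHBA, fell, with the same 20 and 1 adjusted over the list alone (camera adjusted p = 1.71e-20, and adjusted p = 0.0377 with an estimated correlation). CSH1 and CSH2, placental lactogen genes that are nearly identical, had 71 and 57 counts against 0 in shGFP, at least 30.7-fold and 24.7-fold higher. The PSG family, secreted pregnancy-specific glycoproteins, had 6 rises among 10 (9 adjusted over the list alone), with PSG3 at 88.8 ± 22.2 against 3.18 ± 0.945 CPM and PSG9 up by 2.61 (SE 0.31) on the log2 scale (adjusted p = 2.88e-09, and 0.308 with an estimated correlation). Of 14 cell fusion and ST regulators, 7 rose, among them the lipid transporter MFSD2A (5.29, SE 0.47), the cofactor HOPX (3.96), the retroviral envelope gene ERVV-1 (3.13) and the transcription factor TBX3 (1.93), and 1 fell, CREB3L1 (-0.93), named after its values were seen (7 and 1 adjusted over the list alone). The list's adjusted p was 2.78e-04, and adjusted p = 0.217 with an estimated correlation. Of 19 stem and cytotrophoblast genes, 5 rose and 0 fell over all genes and adjusted over the list alone, including PEG10 (1.12, SE 0.16), TFAP2C (0.84) and VGLL1 (0.74), with no list call (adjusted p = 0.0866; 0.0190 without shGFP replicate 1). The extravillous trophoblast list names genes of the invasive lineage, but 13 of its 14 members measured in the inducible table rose on ST differentiation. Of its 13 members measured here, 4 rose and 2 fell on KD1 (6 and 2 adjusted over the list alone; adjusted p = 0.0883, and 0.0339 without shGFP replicate 1). DIO2 (4.57, SE 0.55), HTRA4 (3.16) and ITGA1 (1.75) rose, and fibronectin FN1 fell (-1.96, SE 0.14). The other extravillous faller, named after its values were seen, was the transcription factor ASCL2 (-1.07), which was not called without KD1 replicate 2 or 3, each leaving 1 faller.

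Among the BMP target and homeobox genes, MSX1, the close relative of MSX2, fell (-1.95, SE 0.27), as did HAND1 (-1.50, SE 0.29) and the BMP inhibitor BAMBI. DLX3 (0.85) and BMP7 (0.54, named after its values were seen) rose. This made 2 rises and 3 falls of 14 (2 and 4 adjusted over the list alone; adjusted p = 0.230), with 5 falls without KD1 replicate 1 and 1 rise without shGFP replicate 2 or 3 or KD1 replicate 3. The proliferation list had 5 rises of 24 over all genes and adjusted over the list alone, such as PCNA (0.84) and E2F1 (0.83), with adjusted p = 0.0417 and, as adjusted p = 0.458 with an estimated correlation, no call. That call was lost without shGFP replicate 1 (0.104; 2 rises) and KD1 replicate 1 (0.0553), 2 (0.0653; 2 rises) or 3 (0.0548; 1 rise), and the rises were 1 and 0 without shGFP replicates 2 and 3. Keratins and squamous genes fell in 3 of 10 cases, KRT6A (-2.21), KRT17 (-1.21) and KRT10 (-0.90), or 5 adjusted over the list alone, with adjusted p = 0.0245 and adjusted p = 0.482 with an estimated correlation. The keratin call was lost without shGFP replicate 2 (0.0769; 0 falls) and KD1 replicate 1 (0.105), and 1 member fell without shGFP replicate 3 or KD1 replicate 3. Interferon genes passed as a list (adjusted p = 0.000359, and 0.577 with an estimated correlation) with 1 rise of 18, IFIH1 (1.30), and 13 adjusted over the list alone. KD1 replicate 1 stood apart in these genes, with the interferon-induced IFI6, named after its values were seen, at 8405 CPM against 2913 and 3720 in KD1 replicates 2 and 3. Without KD1 replicate 1 the list's adjusted p was 0.235, and the rises were 0 without any 1 of the shGFP libraries, 5 without KD1 replicate 2 and 2 without KD1 replicate 3.

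The other lists were not called for KD1. Of 13 p53 targets, 4 rose, including the stress cytokine GDF15 (1.91, SE 0.26) and BBC3 (0.93), and 2 fell (adjusted p = 0.277). There were 2 rises without shGFP replicate 3 or KD1 replicate 2, and 1 fall without shGFP replicate 1 and 0 without shGFP replicate 2 or 3 or KD1 replicate 2 or 3. Of 17 hypoxia and glycolysis genes, the glucose transporter SLC2A1 (1.00, SE 0.12) and ADM (0.77) rose and the glucose transporter SLC2A3 fell (-0.82, SE 0.11; adjusted p = 0.678). Among 18 cholesterol synthesis genes the LDL receptor LDLR fell (-0.68, SE 0.12) and 2 rose (adjusted p = 0.657; 1 and 0 rises without shGFP replicates 2 and 3, and 2 falls without KD1 replicate 1). Of 7 stromal genes, POSTN (3.61, SE 0.73) and the collagen COL1A2 (1.06, SE 0.14) rose (adjusted p = 0.646; the median was -0.21 while the test pointed up). Of 7 amnion genes, ITGB6 (-1.67, SE 0.22) and IGFBP3 (-3.80, SE 0.76) fell (adjusted p = 0.236; the median was 0.06 while the test pointed down). Among 24 SWI/SNF subunits 1 was called, DPF3 (-0.90; adjusted p = 0.678 for the list), and it was not called without shGFP replicate 2 or 3 or KD1 replicate 2 or 3. Of 4 endothelial and immune genes 1, CDH5 (0.56), was called (adjusted p = 0.933), and it too was not called without shGFP replicate 2 or 3 or KD1 replicate 2 or 3. By edgeR, 0 of 12 cAMP immediate response genes (adjusted p = 0.475) and 0 of 13 mitochondrially encoded genes (adjusted p = 0.192; 6 rises and adjusted p = 0.00262 without KD1 replicate 1) were called. With replicate number as a block, 3 cAMP genes rose and 1 fell, and 3 mitochondrially encoded genes rose. Adjusted over the list alone the rises and falls were 4 and 3 for p53 targets, 2 and 3 for hypoxia, and 2 and 2 for stroma.

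**Figure D2:**
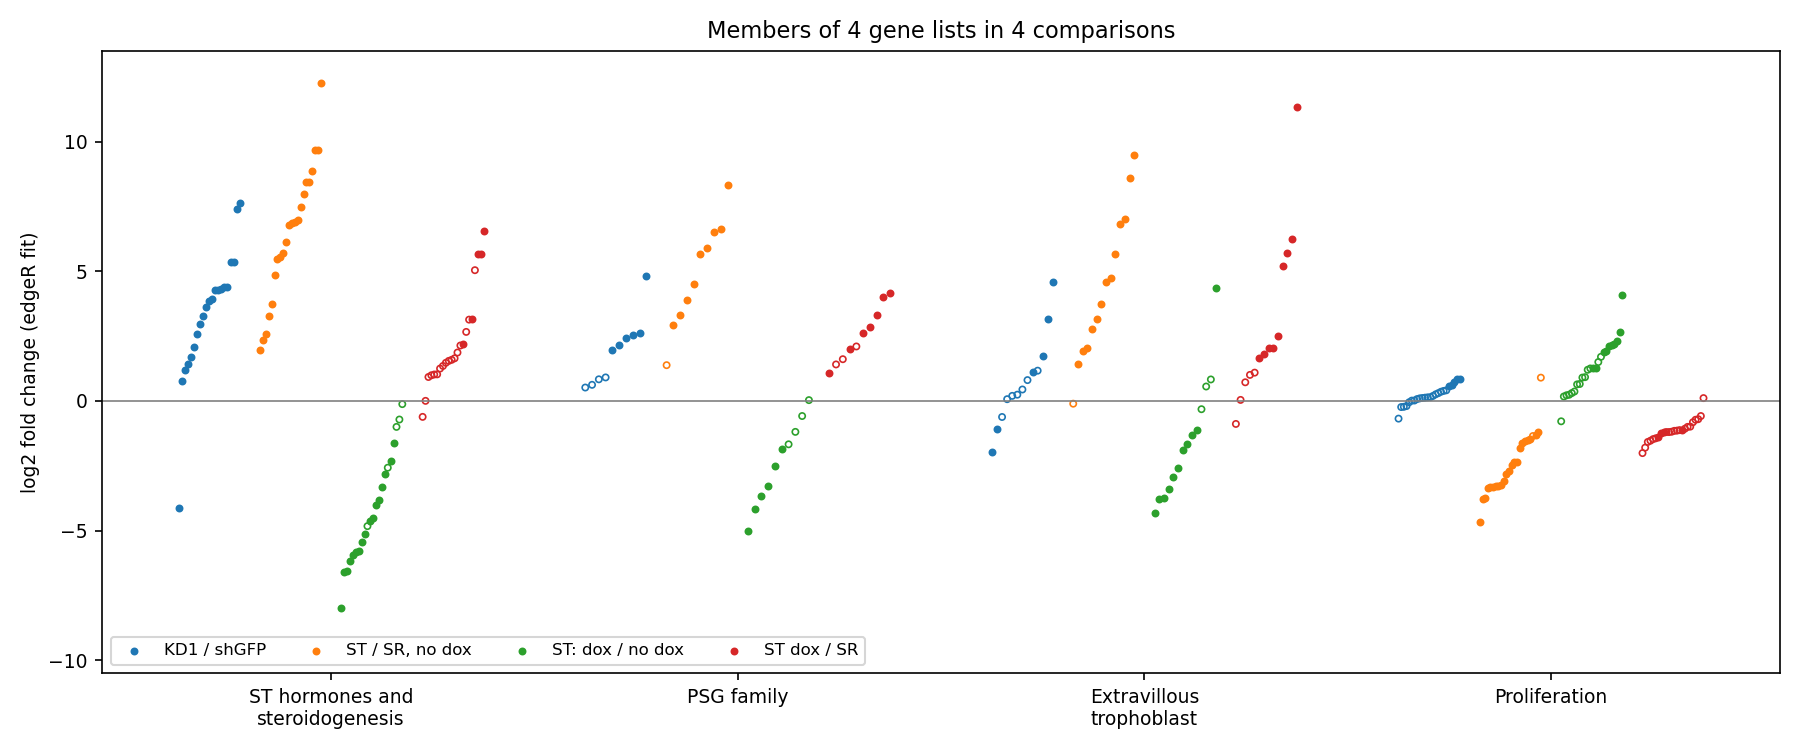
Log2 fold change of every measured member of selected gene lists in 4 comparisons; each point is a gene, filled where it was called and open where it was not. ST hormone genes lie above 0 for KD1 (20 of 21 called higher and 1, INHBA, lower) and for ST differentiation (22 of 22), and below 0 with doxycycline in ST cells (17 of 22 called lower).

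The library labelled KD2 shared the rise of ST genes, while part of its profile differed from KD1. GPR78 (5.66, SE 0.55), LGALS13 (4.31, SE 0.32), MFSD2A (4.26, SE 0.55) and PSG3 (3.45, SE 0.32) were again among the large rises, together with the nitric oxide synthase NOS2 (4.87, SE 0.42). HSD11B2, the placental enzyme that inactivates cortisol, rose from 11.1 ± 2.44 CPM (shGFP, n = 3) to 167 CPM (1 library). Falls absent from KD1 included CKAP4, a membrane protein of the endoplasmic reticulum, at 4.01 CPM against 38.3 ± 5.49 in shGFP and 39.7 ± 6.08 in KD1, and LAGE3 at 1.42 against 12.1 ± 3.29 CPM. Of 21 ST hormone genes 14 rose (19 adjusted over the list alone; adjusted p = 9.93e-17, and 0.0377 with an estimated correlation). Fusion genes (5 rises of 14, 8 adjusted over the list alone, adjusted p = 1.50e-05), stem genes (3 of 19, 8 adjusted over the list alone, 0.00130) and extravillous genes (3 of 13, 5 adjusted over the list alone, 0.00153) passed as lists. Without KD1 replicate 1 they had 8, 8 and 6 rises, and 1 stem gene rose without shGFP replicate 2 or 3. With an estimated correlation their adjusted p were 0.200, 0.308 and 0.308. Interferon genes passed (2 rises of 18, IFIH1 and STAT1, and 14 adjusted over the list alone; adjusted p = 1.31e-08, and 0.458 with an estimated correlation), with 0 rises without any 1 shGFP library or with the block and 16 without KD1 replicate 1. The PSG family (3 rises of 10; adjusted p = 0.0273, and 0.586 with an estimated correlation) was not called without shGFP replicate 1 (0.0774), and 1 gene rose without shGFP replicate 1 or 2 or KD1 replicate 2. The p53 targets (3 rises of 13, including CDKN1A; adjusted p = 0.0482, and 0.308 with an estimated correlation) were not called without KD1 replicate 2 (0.0576). The cAMP list (1 rise of 12, JUNB, 2.33; adjusted p = 0.00497) had adjusted p = 0.577 with an estimated correlation, with 2 rises without shGFP replicate 1 and 3 without KD1 replicate 1, and was not called with the block (adjusted p = 0.129). In all, 704 genes changed by edgeR, 544 up and 160 down, with 326 without shGFP replicate 2, 298 without shGFP replicate 3, 1723 without KD1 replicate 1 and 1230 with the block.

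Across the 15075 genes the fold changes of KD1 and of the library labelled KD2 correlated at 0.567, against 0.306 in simulations with no effect, where only the shared shGFP libraries tie them, and 68.2% had the same sign against 61.1%. The simulations hold no effect of replicate number, no correlation between genes and no systematic difference of the shGFP group. The library labelled KD2 is also replicate 1. Without KD1 replicate 1 the correlation was 0.534. The covariance was 0.340 against a simulated 0.0620 (SD 0.00246), a difference of 0.278. Of the 920 genes that rose on KD1, 841 were higher in KD2 and 348 were called. Of the 410 that fell, 307 were lower and 36 were called, and 10 genes in all were called in opposite directions. The difference between KD2 and KD1, tested directly, was called at 231 genes, among them INHBA (3.87, SE 0.32), ANKRD1 (3.85, SE 0.33), the protease inhibitor CSTA (2.72, SE 0.23) and FN1 (2.21, SE 0.18), all higher in KD2. CKAP4 (-3.31, SE 0.32), REEP6 (-3.02, SE 0.32) and the tight junction gene CLDN3 (-2.59, SE 0.30) were lower in KD2. As a list, PSG genes were lower in KD2 than in KD1 (1 of 10 called, PSG1, which was not called without KD1 replicate 2, and 6 adjusted over the list alone; adjusted p = 2.19e-06, and 0.374 with an estimated correlation). ST hormones (adjusted p = 0.0145) and mitochondrially encoded genes (0.0417), read as a sign of RNA quality, were also lower as lists, and BMP targets (0.00147), interferon (0.000787) and cAMP genes (0.00780) were higher. With an estimated correlation these had adjusted p = 0.308, 0.577, 0.308, 0.586 and 0.579. Without KD1 replicate 2 and 3 in turn, the mitochondrial list (0.126 and 0.189) and the cAMP list (0.0653 and 0.0700) were not called, nor the ST hormones without replicate 3 (0.0565). With the block the BMP (adjusted p = 0.0617), interferon (0.788), cAMP (0.924) and mitochondrial (0.807) lists were not called, and keratins were higher as a list (0.00218). The count was 114 without shGFP replicate 2, 127 without shGFP replicate 3, 911 without KD1 replicate 1, 48 without KD1 replicate 2, 68 without KD1 replicate 3 and 479 with the block.

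ST differentiation without doxycycline raised the RNA of hormone genes and lowered that of most proliferation genes. LEP rose from 0.939 ± 0.404 to 4803 ± 3226 CPM (log2 fold change 12.25, SE 0.83), INHA, the inhibin alpha subunit, from 0.714 ± 0.170 to 347 ± 77.4 CPM (8.87, SE 0.43). HTRA4, a placental serine protease, rose from 1.81 ± 0.416 to 710 ± 213 CPM (8.58, SE 0.39; n = 3 and 3). The iodothyronine deiodinase DIO2 (9.48, SE 0.72), the metalloprotease ADAM12 (9.53, SE 1.37) and PSG3 (8.32, SE 0.64) rose too. MUCL1 and PAEP had no counts in SR cells and were at least 183-fold and 64.1-fold higher in ST cells. Falls included IGDCC3 (-6.96, SE 0.61), the intermediate filament vimentin (VIM, -6.14, SE 0.83) and the growth factor BMP7 (-4.22, SE 0.34). In all, 4637 of 13087 genes changed, 2557 up and 2080 down, with 2827 without SR replicate 2 and 3051 without SR replicate 3.

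All 22 measured ST hormone genes rose (22 adjusted over the list alone; adjusted p = 9.22e-14, and 0.308 with an estimated correlation). So did 9 of 10 PSG genes (3.82e-08, and adjusted p = 0.308 with an estimated correlation) and 13 of 14 extravillous genes, with FSTL3 up by 6.81 (SE 0.74; adjusted p = 1.01e-08, and 0.200 with an estimated correlation). Of 14 fusion genes 8 rose, including MFSD2A (5.90, SE 0.80), ERVV-1 (5.24, SE 0.70) and HOPX (4.83, SE 0.52), with adjusted p = 0.00179, and 0.328 with an estimated correlation. Of 24 proliferation genes 22 fell, with the division marker MKI67 down from 308 ± 46.2 to 22.4 ± 6.04 CPM, CDC20 at -3.76 (SE 0.55) and BIRC5 at -3.36 (SE 0.51; adjusted p = 2.61e-12, and 0.308 with an estimated correlation). Of 19 stem and cytotrophoblast genes 9 fell and 2 rose (10 and 3 adjusted over the list alone), with the lipoprotein receptor LRP2 down from 963 ± 192 to 33.2 ± 21 CPM, TEAD4 at -3.48 (SE 0.47) and PEG10 at -3.22 (SE 0.41). EGFR, a member of this list, rose (3.67, SE 0.53). The stem list had adjusted p = 0.0332, and 0.418 with an estimated correlation, and was not called without SR replicate 1 (0.101). Interferon genes rose in 13 of 16 cases (15 adjusted over the list alone), such as MX1 (6.09, SE 0.81) and OAS3 (5.65, SE 0.60), with adjusted p = 3.50e-05, and 0.390 with an estimated correlation. Of 12 cAMP immediate response genes 10 rose, such as FOSB (3.95, SE 0.40), JUNB (3.89, SE 0.37) and ATF3 (2.78, SE 0.25), with adjusted p = 1.13e-05, and 0.217 with an estimated correlation.

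Mitochondrially encoded genes, read as a sign of RNA quality, rose in 6 of 13 cases (7 adjusted over the list alone; adjusted p = 0.0206, and 0.620 with an estimated correlation). ST without doxycycline replicate 1 stood apart here, with 40.9% of its counts on the mitochondrial genome against 12.4% to 22.1% in the other 7 libraries and CGA at 3.57% of counts against 9.76% and 8.55% in its replicates. Without that library the list was not called (0.156; 3 rises), nor without SR replicate 1 (0.0697; 1 rise), and the rises were 1 and 2 without SR replicates 2 and 3 and 3 without either doxycycline library. Of the lists without a call on differentiation, BMP targets had 6 rises and 6 falls of 13 (adjusted p = 0.919), and MSX1 fell (-3.17, SE 0.64). Hypoxia genes had 5 rises and 1 fall of 17, with NDRG1 at 4.30 (SE 0.31; adjusted p = 0.0640, called without SR replicate 1 at 0.0498 and without ST without doxycycline replicate 3 at 0.0147). Endothelial and immune genes had 2 rises of 4, with CDH5 at 2.67 (SE 0.26; adjusted p = 0.0553, called without SR replicate 3 at 0.0200 and without ST without doxycycline replicate 2 at 0.0436). SWI/SNF subunits had 2 rises and 4 falls of 25, with SMARCA2, 1 of its ATPases, at -1.40 (SE 0.25; adjusted p = 0.306). The p53 targets had 3 rises and 2 falls of 13, with GDF15 at 4.04 (SE 0.56; 0.863), and cholesterol genes 1 rise and 2 falls of 19, with DHCR24 at -2.38 (SE 0.34; 0.513). Stromal genes had 1 rise and 2 falls of 5, with COL1A2 at -3.23 (SE 0.36; 0.700). Amnion genes had 4 rises of 7, with IGFBP3 at 8.62 (SE 0.95) and HEY1 at 4.11 (SE 0.36; 0.193), and keratins 1 rise and 2 falls of 8, with the basal desmosomal DSG3 at -3.84 (SE 0.52; 0.339). The SWI/SNF rises were 0 without any 1 SR library or ST without doxycycline replicate 3, and the falls 2 without SR replicate 1 or 3 or that ST library. The hypoxia fall was absent without any 1 SR library, the cholesterol rise without SR replicate 2 or 3 or ST without doxycycline replicate 2, and the endothelial rises were 1 without any 1 SR library or ST without doxycycline replicate 2.

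With doxycycline during ST differentiation, 17 of 22 ST hormone genes were called lower and 10 of 24 proliferation genes higher. All of these cells carried the inducible construct, so an effect of doxycycline itself is not separated from that of MSX2. LEP fell from 4803 ± 3226 CPM in ST cells without doxycycline (n = 3) to 49.7 ± 16.6 CPM with it (n = 2; log2 fold change -6.60, SE 0.77), and PSG6 fell from 591 ± 126 to 46.6 ± 1.09 CPM (-3.66, SE 0.38). The division marker MKI67 rose from 22.4 ± 6.04 to 141 ± 8.04 CPM (2.66, SE 0.28). The oxytocin receptor OXTR rose to 667 ± 62.9 CPM (7.03, SE 0.52), and the peptide receptor VIPR2 by 6.72 (SE 0.74). PCAT14, a noncoding RNA, had no counts in ST cells without doxycycline and was at least 93.6-fold higher with it, and involucrin (IVL), a squamous envelope protein, had 382 counts against 1 (ratio 267, counting interval 47.7 to 10590). The sphingolipid enzyme DEGS2 (-6.46, SE 0.73) and the potassium channel KCNA7 (-6.23, SE 0.64) were among the largest falls. In all, 1694 of 13087 genes changed, 902 up and 792 down. The count was 1061 without SR replicate 2, 3380 without ST without doxycycline replicate 1 and 822 without its replicate 2, 408 and 253 without ST with doxycycline replicate 2 or 3 (which leaves 1 doxycycline library), and 534 in a fit of only these groups.

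Of 22 ST hormone genes 17 fell with doxycycline and 0 rose (19 adjusted over the list alone; adjusted p = 1.93e-14, and 0.308 with an estimated correlation). All 17 kept the call without ST without doxycycline replicate 1, the library with the high mitochondrial share. The PSG family had 6 falls of 10 (7 adjusted over the list alone), with PSG4 at -5.04 (SE 0.58) and PSG3 at -4.17 (SE 0.58; adjusted p = 1.56e-07, and 0.308 with an estimated correlation). Fusion genes had 7 falls of 14 over all genes and adjusted over the list alone, including the ST transcription factor GCM1 (-2.45, SE 0.41, not called without ST with doxycycline replicate 3; 0.000580, and adjusted p = 0.308 with an estimated correlation). Extravillous genes had 10 falls of 14, with HTRA4 at -3.39 (SE 0.35), and 1 rise, PRG2 (4.34, not called without ST with doxycycline replicate 2; 0.000176, and adjusted p = 0.308 with an estimated correlation). Proliferation genes had 10 rises of 24 (13 adjusted over the list alone; adjusted p = 4.96e-07, and 0.375 with an estimated correlation). cAMP immediate response genes had 5 falls of 12 (7 adjusted over the list alone), with ATF3 at -1.89 (SE 0.28; 0.000176, and adjusted p = 0.250 with an estimated correlation). With doxycycline replicate 2 or 3 left out, the falls were 11 and 4 for ST hormones, 4 and 5 for PSG, 1 and 0 for fusion (4 without ST without doxycycline replicate 2), 1 and 2 for extravillous and 1 and 1 for cAMP genes, and the proliferation rises were 2 and 2. The proliferation rises were 6, 5 and 6 without SR replicates 1 to 3 and 18 and 3 without ST without doxycycline replicates 1 and 2, and the cAMP falls were 8 and 2 without those same ST libraries. Each of these 6 list calls was kept whichever library was left out.

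Of the remaining lists, the hypoxia and the mitochondrially encoded genes were called with doxycycline. BMP targets had 4 rises of 13, including BMP7 (4.52, SE 0.36), HAND1 (2.74, SE 0.43) and MSX1 (3.75), and 1 fall, BMP4 (adjusted p = 0.241; 5 and 2 adjusted over the list alone). Hypoxia genes had 4 falls of 17, such as ADM (-2.41; adjusted p = 0.0291, and 0.308 with an estimated correlation), and were not called without ST without doxycycline replicate 1 (0.112) or with the block (0.0643). The interferon (0.0364) and cholesterol (0.0204) lists were called lower with the block. Mitochondrially encoded genes had 2 falls of 13, ND1 and ND4L (adjusted p = 0.00153, and 0.550 with an estimated correlation). This list call was kept whichever library was left out, with 2 falls without ST without doxycycline replicate 1, the library with the high mitochondrial share, and 0 without SR replicate 2 or 3 or either doxycycline library. Stem genes had 3 rises and 1 fall of 19 (0.587), with LRP2 at 2.23, TEAD4 at 1.87 and ITGA6 at 1.47. SWI/SNF subunits had 1 rise, DPF3 (3.43, SE 0.35; 0.666). The p53 targets had 2 rises and 2 falls with ZMAT3 at 1.76 (SE 0.28; 0.0629, and 0.0259 without ST without doxycycline replicate 2), and cholesterol genes 2 rises and 2 falls (0.0866, and 0.00647 without ST without doxycycline replicate 1). Interferon genes had 1 fall of 16, OASL (0.174), and amnion genes 2 rises and 1 fall of 7 with VTCN1 at 3.67 (SE 0.53) and HEY1 at -3.95 (SE 0.41). Endothelial genes had 1 fall, CDH5 (-2.58, SE 0.31), and keratins 3 rises, such as KRT6A (5.66), and 1 fall (0.0866, and 0.0149 without ST without doxycycline replicate 1). Stromal genes had 2 rises of 5, PDGFRB and COL1A2 (called as a list at 0.0489 without ST without doxycycline replicate 2 alone). Apart from DPF3, ZMAT3, BMP7, HAND1, VTCN1, HEY1 and CDH5, the genes named in this part for doxycycline lost their calls without ST with doxycycline replicate 2 or 3, or both. Without replicate 2 and 3 in turn, 0 and 0 stem genes rose, 1 and 0 hypoxia genes fell, 1 and 1 keratins rose, and 1 and 0 stromal genes rose. Without ST without doxycycline replicate 1, the falls were 4 for interferon and 8 for cholesterol genes, and the rises 5 for stem genes, 4 for p53 targets and 5 for keratins.

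The genes of ST differentiation moved back with doxycycline to different extents. Of 2557 genes higher on differentiation, 661 were called lower with doxycycline and 43 higher, and of 2080 lower genes 499 were called higher and 6 lower. The median log2 fold change against SR cells of the 2557 was 1.97 without and 0.95 with doxycycline, and that of the 2080 was -1.48 and -0.83. Both sets were chosen by their change without doxycycline, so part of the difference between these medians may come from that choice. The covariance of both fold changes across genes was -1.33 against -0.121 in simulations where only the shared ST libraries tie them, a difference of -1.21. With the shared libraries split, so that differentiation and doxycycline used different ST libraries, 60.3%, 82.6% and 81.1% of called genes had opposite signs with replicates 1, 2 and 3 held out for doxycycline. Against SR cells, ST cells with doxycycline kept high levels of FN1 (3464 ± 1112 against 46.2 ± 10.9 CPM, 6.23, SE 0.44), INHA (6.56, SE 0.42), HTRA4 (5.18, SE 0.36) and the steroid enzyme HSD3B1 (3.16, SE 0.31). The same held for PSG9 (4.02, SE 0.37), the protease HTRA1 (9.29, SE 0.96) and IGFBP3 (8.51, SE 0.97). DUSP6, a brake on ERK signalling (-5.81, SE 0.56), the stem cell factor SALL4 (-4.75, SE 0.37), TWIST1 (-4.38, SE 0.55) and BMP4 (-3.96, SE 0.62) were among the falls.

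In that last comparison, ST hormones had 5 rises of 22 (8 adjusted over the list alone; adjusted p = 0.000271, and 0.478 with an estimated correlation). PSG genes had 7 of 10 (9 adjusted over the list alone; 1.25e-05, and adjusted p = 0.328 with an estimated correlation) and extravillous genes had 9 of 14 (3.16e-06, and adjusted p = 0.217 with an estimated correlation). Proliferation genes had 4 falls of 24 (14 adjusted over the list alone; 1.01e-08, and adjusted p = 0.328 with an estimated correlation), with MKI67 at -1.12. Interferon genes had 8 rises of 16, such as IFIT2 (5.56, SE 0.73; adjusted p = 0.000176, and 0.418 with an estimated correlation), and cAMP genes 5 of 12, such as FOSB (2.84, SE 0.41; 0.00701, and adjusted p = 0.308 with an estimated correlation). Stem genes had 4 falls and 1 rise, with PEG10 at -2.83 (SE 0.47; adjusted p = 0.0139, and 0.374 with an estimated correlation; 0.0716 without SR replicate 1, 0.0737 with the block). Cholesterol genes (0.00320, direction down) and p53 targets (0.0120, direction up, and 0.0753 without ST with doxycycline replicate 2) passed too, with adjusted p = 0.550 and 0.328 with an estimated correlation. The other lists were not called, but fusion genes were without SR replicate 1 (0.0262) or ST with doxycycline replicate 3 (0.0224), and BMP targets without the latter (0.00579). The change was called at 1754 genes, 1122 up and 632 down. The count was 912, 501 and 662 without SR replicates 1, 2 and 3, 3219 and 3237 without ST without doxycycline replicates 1 and 3, 485 and 405 without ST with doxycycline replicates 2 and 3, and 4304 in a fit of only these groups. The ST hormone rises were 10 without ST without doxycycline replicate 1 or 3, and the proliferation falls 17 and 16. They were 0 and 2 without SR replicates 2 and 3, and 1 and 0 without ST with doxycycline replicates 2 and 3, where interferon rises were 2 and 3 and cAMP rises 1 and 1. Without SR replicates 1, 2 and 3 the interferon rises were 4, 3 and 3, the cAMP rises 3, 2 and 2 and the stem falls 2 each, and PSG rises were 4 without SR replicate 2 or 3 or ST with doxycycline replicate 2.

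Genes that rose on knockdown overlapped those that rose on differentiation and those that were lower with doxycycline. These overlaps are not separate findings, because the differentiation and doxycycline calls share the ST libraries without doxycycline. Of the 792 genes lower with doxycycline, 661 were higher on differentiation. Of the 902 genes higher with doxycycline, 499 were lower on differentiation. Whether the overlap of KD1 with doxycycline goes beyond that with differentiation was not tested. Of 907 genes higher on KD1 and tested in both tables, 496 were also higher on ST differentiation, where 170 would be shared by independent sets (odds ratio 6.34, 95% interval 5.50 to 7.31, Fisher's exact test, adjusted p = 7.88e-141). With doxycycline, 263 of them were lower against 53.7 (odds ratio 9.46, 7.95 to 11.3, adjusted p = 1.77e-120), and 48 were higher against 60.7 (0.766, 0.556 to 1.04, adjusted p = 0.0845). Of 372 genes lower on KD1, 112 were lower on differentiation against 60.8 (odds ratio 2.28, 1.80 to 2.87, adjusted p = 3.51e-11) and 73 were higher with doxycycline against 24.9 (3.63, 2.75 to 4.76, adjusted p = 7.57e-17). The crossed pairs were below independence, 86 against 148 for higher on KD1 and lower on differentiation (0.516, 0.406 to 0.649, adjusted p = 1.37e-09), and 44 against 69.8 for lower and higher (0.573, 0.407 to 0.789, adjusted p = 0.000448). There were 10 against 22 for lower on both KD1 and doxycycline (0.431, 0.204 to 0.807, adjusted p = 0.00572). With DESeq2 calls the first of these crossed odds ratios was 1.11 and the second 0.847, both without a call. With DESeq2 that for higher on both KD1 and doxycycline was 1.42 and called above 1 (Fisher's exact test, adjusted p = 0.00914). The DESeq2 overlaps took as background all genes with any count in each table, also those that DESeq2 gave no adjusted p. This larger background raises each odds ratio, so these values are not comparable with the edgeR ones. With a 2-fold minimum the second and the last were 0.709 and 0.498, and at an adjusted p below 0.01 they were 1.08 and 1.02, all without a call. The first was 0.324 and 0.322 without shGFP replicates 2 and 3 and 0.320 without KD1 replicate 3, and the second was not called without shGFP replicate 2 (0.641) or 3 (0.669) or KD1 replicate 2 (0.640). The last was 0.258 without shGFP replicate 1. It was not called without shGFP replicate 2 (0.642) or 3 (0.604), KD1 replicate 2 (0.554) or 3 (0.485), SR replicate 2 (0.523), ST without doxycycline replicate 2 (0.723) or ST with doxycycline replicate 2 (0) or 3 (0.576). The odds ratio for higher on both KD1 and doxycycline was called below 1 without shGFP replicate 2 (0.541) or 3 (0.626), KD1 replicate 1 (0.688) or 3 (0.641) or ST without doxycycline replicate 1 (0.675). That for higher on KD1 and lower with doxycycline was 5.91 without ST without doxycycline replicate 1, 19.4 and 15.0 without ST with doxycycline replicates 2 and 3 and 5.63 with the block. That for lower on KD1 and higher with doxycycline was 6.23 without ST with doxycycline replicate 2. Across 12635 genes the KD1 fold change correlated at 0.339 with differentiation and -0.291 with doxycycline, with genes not independent replicates.

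**Figure D3:**
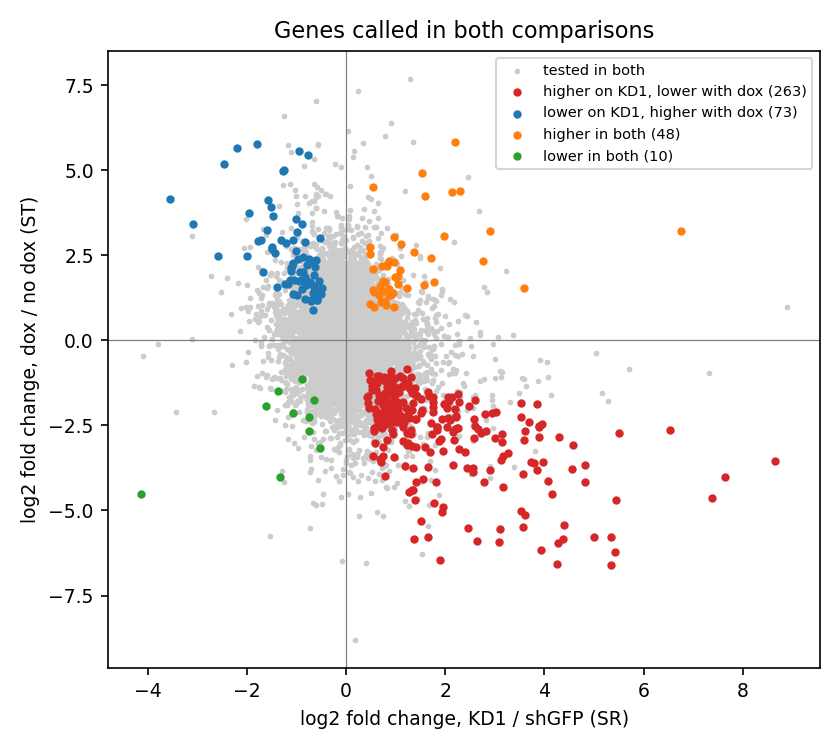
Log2 fold change on KD1 (x axis) against log2 fold change with doxycycline in ST cells (y axis) for genes tested in both tables; each point is a gene. Of 907 genes called higher on KD1, 623 lie below 0 on the y axis and 263 are called lower there.

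MSX2 binding lay mostly away from gene starts and coincided with SWI/SNF peaks. The list held 11494 peaks over 11.1 Mb with a median length of 872 bp, 7.6% within 1 kb of an annotated gene start, 19.6% within 5 kb and 76% within 50 kb, and 62.1% lay inside a gene interval. In untransduced cells 71.2% of MSX2 peaks overlapped an ARID1A peak (0.858% for shuffled peaks), 54.8% a SMARCA4 peak (0.552%) and 51% a peak of H3K27ac, the mark of active regulatory regions (2.17%). Shuffled peaks could fall anywhere along their chromosome. The excess over them therefore does not tell a tie to SWI/SNF from a shared preference for active regulatory regions. Peaks of both ARID1A and SMARCA4 were found at 51.6% of MSX2 peaks. The Polycomb mark H3K27me3 covered 0.7% (2.05% for shuffled peaks) and the heterochromatin mark H3K9me3 2.1% (1.75%), and 17.7% carried none of these 5. In MSX2 knockdown cells the shares were 85.2% for ARID1A, 82.2% for SMARCA4, 64.5% for H3K27ac, 0.6% for H3K27me3 and 2.9% for H3K9me3, and 1.35%, 1.35%, 2.68%, 5.21% and 2.86% for shuffled peaks. The ratio to shuffled peaks in knockdown and untransduced cells was 63.1 and 83 for ARID1A, 61.1 and 99.2 for SMARCA4, and 24 and 23.6 for H3K27ac. With 1.35% of shuffled peaks covered, even full coverage of the MSX2 peaks would give ARID1A and SMARCA4 ratios below the untransduced ones. The lower ratios therefore do not tell whether these factors coincided less with MSX2 peaks. SMARCA4 peaks were gained at 3332 and lost at 178 MSX2 peaks, ARID1A peaks gained at 1868 and lost at 265, and H3K27ac peaks gained at 1775 and lost at 233. There was 1 list per condition, so no replicate spread stands behind these shares.

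**Figure D4:**
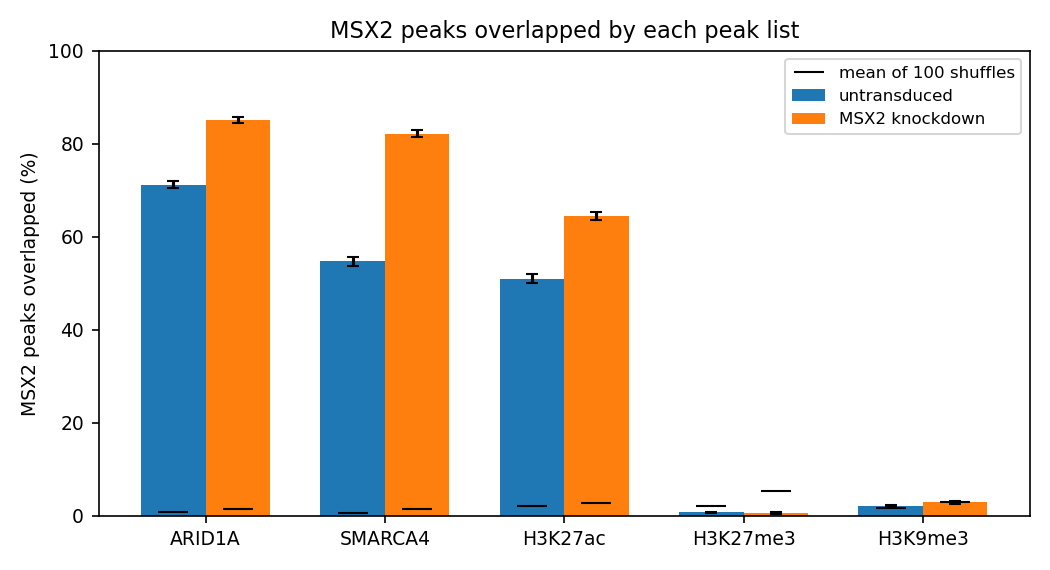
Percent of the 11494 MSX2 peaks overlapped by peaks of each factor or histone mark in untransduced and MSX2 knockdown cells, beside the mean of 100 shuffles; bars start at 0. ARID1A rises from 71.2% to 85.2% and SMARCA4 from 54.8% to 82.2%, while H3K27me3 stays at 0.7% and 0.6%.

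Every list of the 5 antibodies was longer in knockdown cells than in untransduced cells. ARID1A had 15105 and 23317 peaks, SMARCA4 9581 and 21923, H3K27ac 15068 and 19647, H3K27me3 10547 and 25530, and H3K9me3 13130 and 17007. Most untransduced peaks were shared with the knockdown list (88.9%, 92.5%, 88.7%, 84.5% and 86.5% in that order), and fewer knockdown peaks were shared in return (57.3%, 40.1%, 68.0%, 31.9% and 55.9%). The covered length rose from 10.8 to 17.9 Mb for ARID1A, 7.03 to 18.7 Mb for SMARCA4 and 48.1 to 126 Mb for H3K27me3. These comparisons set untransduced cells against transduced cells, and the depth of the ChIP libraries is unknown.

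Genes that rose on KD1 more often had an MSX2 peak within 5 kb of their start, 168 of 920 (18.3%) against 8.3% of genes not called (odds ratio 2.45, 95% interval 2.04 to 2.94, Fisher's exact test, adjusted p = 2.65e-19). Of the 410 that fell, 52 (12.7%) did (1.60, 1.16 to 2.15, adjusted p = 0.00377), which was not called without KD1 replicate 1 (1.18) or 3 (1.49) or with a 50 kb window (1.19). For doxycycline the shares were 14.2% of risen and 15.8% of fallen genes against 8.9% (odds ratios 1.69 and 1.92, adjusted p = 1.21e-06 and 6.20e-09, and 4.58 for fallen genes without ST with doxycycline replicate 3). For ST differentiation without doxycycline they were 11.7% and 12.3% against 8.5% (odds ratios 1.44 and 1.51), so this excess was not particular to doxycycline. Of 263 genes that rose on KD1 and fell with doxycycline, 54 (20.5%) were bound, against 9.6% of other genes (odds ratio 2.44, 1.77 to 3.33, Fisher's exact test, p = 1.41e-07). This share lies near the 18.3% of all genes that rose on KD1, and whether the fall with doxycycline adds to it was not tested. Of 73 genes moving the other way 10 were bound (1.47, 0.669 to 2.89, Fisher's exact test, p = 0.238). PSG3 (minus strand, start at chromosome 19, 42740486) had an MSX2 peak at 42735650 to 42736671 and log2 fold changes of 4.81 on KD1 and -4.17 with doxycycline. INSL4, a placental insulin-like hormone, had a peak over its start (chromosome 9, 5229840 to 5231586) and changes of 3.85 and -3.83. HTRA4 had a peak over its start (chromosome 8, 38973519 to 38974155) with changes of 3.16 and -3.39, and the trophoblast noncoding RNA TCL6 (chromosome 14, 95651036 to 95653687) 3.10 and -5.54. GLDN, BCAR4, RHOBTB1, PSG9, DPEP2 and PSG1 completed the 10 named by the rule, and ITGB6 and BAMBI were among those bound in the reverse direction. The doxycycline calls of GLDN, BCAR4, RHOBTB1, DPEP2 and PSG1 were lost without ST with doxycycline replicate 2 and without replicate 3, those of ITGB6 and BAMBI without replicate 3, and that of ITGB6 also without ST without doxycycline replicate 2.

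Genes that rose on KD1 more often had, within 5 kb of their start, a peak of SWI/SNF subunits in knockdown cells and none in untransduced cells, counted as a gain (and the reverse as a loss). SMARCA4 was gained at 22.6% of these genes against 13.1% of genes not called (odds ratio 1.94, 1.64 to 2.28, adjusted p = 8.82e-13). ARID1A was gained at 10.1% against 5.1% (2.10, 1.65 to 2.64, adjusted p = 4.07e-08) and H3K27ac at 12.4% against 8.8% (1.46, 1.18 to 1.79, adjusted p = 0.00303). SMARCA4 was also lost at 2.2% against 1% (2.24, 1.32 to 3.62, adjusted p = 0.0107), which was not called against genes matched on expression (1.81). With a 50 kb window a gain needs the whole 50 kb to be free of untransduced peaks, so other genes are counted and the values do not test the 5 kb result. The odds ratios there were 1.02, 1.01, 1.18 and 0.784 with no call. At the 410 genes that fell on KD1, 0 of the 10 tests of gains or losses within 5 kb were called by Fisher's exact test at an adjusted or an unadjusted p below 0.05. With the 50 kb window H3K9me3 was gained at 16.8% of them against 12% (odds ratio 1.49, Fisher's exact test, unadjusted p = 0.00437). This was the smallest p at that window and was not adjusted over the tests there. For the same mark and genes the odds ratio was 1.04 with a 1 kb and 1.42 with a 5 kb window (Fisher's exact test, unadjusted p = 0.816 and 0.236).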

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

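In this part, the test of genes called the same way against both groups, with its 4-fold count and its fits with the block, was chosen after the result was seen, as was the comparison of opposite signs with single KD1 libraries; the other tests were planned. A further look for a mixture, also made after the result was seen and not kept, did not exclude one. The difference between the library labelled KD2 and KD1 was tested directly by edgeR and called at 231 genes, 127 higher and 104 lower in KD2. The count was 114 without shGFP replicate 2, 127 without shGFP replicate 3, 911 without KD1 replicate 1, 48 without KD1 replicate 2 and 68 without KD1 replicate 3.

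Each of the following was brought up by that test of the difference between hairpins, on the log2 scale. LTK differed by -4.49 (1.06 on KD1 without a call, -3.43 in KD2). C1orf53 differed by -3.80 (-0.54 on KD1 without a call, -4.34 in KD2). CKAP4 differed by -3.31 (0.05 and -3.26), LAGE3 by -3.05 (-0.03 and -3.08) and MT1E by -2.51 (-0.20 and -2.70), each without a call on KD1. CRYAB differed by -3.08 (5.03 on KD1, 1.95 in KD2 without a call). COL17A1 differed by 2.13 (-3.08 and -0.95), C3 by 2.58 (-3.56 and -0.98), ANKRD1 by 3.85 (-3.11 and 0.74) and INHBA by 3.87 (-4.14 and -0.27), each without a call in KD2. The call on the difference was lost without shGFP replicate 2 or 3 or KD1 replicate 2 or 3 for C1orf53 and C3, and without KD1 replicate 2 or 3 for LTK and CRYAB.

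The library labelled KD2 carried much of the KD1 change while its MSX2 stood at 141 CPM, inside the range of the shGFP libraries. Random noise in the shared shGFP libraries, independent between genes, does not account for the shared change. The covariance of both fold changes was 0.340 against 0.0620 (SD 0.00246) in simulations with such noise and no effect. The simulations held no correlation between genes, no effect of replicate number and no systematic difference of the shGFP group. Whether these add to the shared change stays open. A KD1 or shGFP library, or a mixture of both, under the KD2 label stays open: 104 genes, such as CKAP4, were called the same way against both groups, but KD1 replicate 1 taken alone reached 328, while the other 5 libraries reached 0. Of these, 15 lay at least 4-fold outside both groups in KD2 and 38 in KD1 replicate 1, so values outside both groups do not exclude a further library of either kind, and with replicate number as a block the counts were 238 for KD2, 452 for KD1 replicate 1 and 603 for shGFP replicate 1. The opposite sign was found at 13.7% of KD1 calls, beyond the tenth set as the bound beforehand. That bound may be too low, because KD1 replicate 1 against the other KD1 libraries reached 13.4%, with 0.2% and 0.5% for replicates 2 and 3. With the block the shares were 16.9% for KD2 and 14.4%, 1.4% and 1.7%, each from a single library, so their spread is unknown. The fits behind these values differ: those of KD1 replicate 1 alone took calls and spread without it, and those of KD2 with it. The counts and shares are thus not on equal terms and decide neither way. A hairpin with other targets, or one that lowers the protein and not the RNA, may also account for the pattern and was not tested, with a single library of its kind.

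In ST without doxycycline replicate 1 the mitochondrial genome took 40.9% of counts, against 12.4% to 22.1% in the other libraries of the table. This library alone does not account for the fall of ST hormone genes with doxycycline, since all 17 members called lower were still called lower without it. For the mitochondrially encoded genes themselves it stays open: of 6 members called higher on differentiation, 3 were still called without it, between the bounds set beforehand. A lower RNA quality of that library may explain the remainder, and no biological explanation was tested for it.

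Each of the 5 antibodies had more peaks in knockdown than in untransduced cells, from 1.30-fold to 2.42-fold. More peaks called everywhere, from depth, enrichment or calling, stays open. The odds ratios for a knockdown-only peak to lie at an MSX2 peak were at most 0.595, so knockdown-only peaks lay there less often than shared peaks, which met neither of the outcomes set beforehand, and the lists for H3K27me3 and H3K9me3 grew as well. For ARID1A and SMARCA4 a value above 1 could hardly be reached, because most MSX2 peaks already had an untransduced peak. Of MSX2 peaks without one, 1868 had an ARID1A peak in knockdown cells and 1441 did not. For SMARCA4 these were 3332 and 1868. For these factors the odds ratios therefore cannot decide. Gained active marks at genes that rise on knockdown (a peak within 5 kb in knockdown cells alone) had a smallest odds ratio of 1.46, as that explanation needs, but SMARCA4 losses were also more frequent there (not called against genes matched on expression, 1.81). Transduction itself cannot be told apart from knockdown, because the untransduced cells carried no hairpin.

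For KD1 against shGFP, 1 of 10 splits of the 6 libraries, the real one, gave as many as 1330 genes, and the highest of the others gave 0 (edgeR). Among the 4 splits that part every numbered pair, the other 3 also gave 0. For ST without doxycycline against SR, 1 of 10 splits gave as many as 4637 genes, and the highest of the others gave 0 (edgeR). With 10 splits a share under 0.05 cannot be reached.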

How the results depend on the processing

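In this part, the fits without the mitochondrial genome's counts were chosen after seeing the data; all others were planned. Over the main results, 372 values stayed on their side of the threshold or within the spread, 59 moved, 7 became called, 21 lost their call and 5 reversed. For lists in each comparison 2089 stayed, 50 became called and 90 lost the call (7 of them with the replicate block, none for KD1), and for named genes 5739 stayed, 23 became called, 575 lost the call and 0 reversed. Except where the alternative itself tests fewer or more genes or libraries, the cause was not tested. Recovery was limited at this depth and number of libraries, with simulated 2-fold changes recovered in 43.8% of cases for KD1 and 0% for doxycycline. Alternatives that needed peak scores (the MSX2 peaks above the median score, equal numbers of top peaks) and fits of only KD2 and its comparison group were not run. Where a left-out library leaves a single one in its group, that library was assumed to vary like the others.

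Leaving out each library in turn, genes changed ranged from 702 to 2223 for KD1, 298 to 1723 for the library labelled KD2, 48 to 911 for their difference, 2827 to 5985 for ST differentiation, 253 to 3380 for doxycycline in ST cells and 405 to 3237 for ST cells with doxycycline against SR. The lists called ranged from 32 to 50, where 32 was without the library labelled KD2 and so without the 14 list calls of its 2 comparisons, and the lowest with every comparison in place was 43. Without a filter on low counts 1271 genes changed in KD2, 591 in the difference, 2635 with doxycycline and 2642 for ST cells with doxycycline against SR. With the replicate block the counts were 2246 for KD1, 1230 for KD2 and 479 for the difference, and with the DESeq2 test 1160 for KD2 and 567 for the difference. A 2-fold minimum left 667 genes for KD1. Fits of only the groups compared gave 534 genes with doxycycline and 4304 against SR. With an estimated correlation 2 lists were called. Without the mitochondrial genome's counts 4642, 1704 and 1761 genes changed on differentiation, with doxycycline and against SR, and 44 lists were called.

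For overlaps of KD1 with differentiation, leaving out libraries gave odds ratios of 0.320 to 0.671 for higher and lower and 0.489 to 0.702 for lower and higher, and with doxycycline 0.541 to 1.13 for higher and higher and 0 to 0.723 for lower and lower. DESeq2 calls gave 1.11 for higher and lower and 0.847 for lower and higher, both without a call, and 1.42 for higher on both KD1 and doxycycline, called above 1 (Fisher's exact test, adjusted p = 0.00914). The background for DESeq2 was larger, all genes with any count in each table, which by itself raises the odds ratios. A 2-fold minimum gave 0.709 for lower and higher on differentiation and 0.498 for lower on both KD1 and doxycycline, and an adjusted p below 0.01 gave 1.08 and 1.02 for these, all without a call. The same-direction overlaps with differentiation and the opposite-direction overlaps with doxycycline kept their call in every setting run. With ST libraries split between both fold changes, the correlation of doxycycline with differentiation was -0.209, -0.433 and -0.473 with replicates 1, 2 and 3 held out, and 60.3% and 81.1% of called genes were opposite with replicates 1 and 3.

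MSX2 peaks near genes that fell on KD1 had odds ratios of 1.18 to 2.06 with libraries left out and 1.19 with the 50 kb window. For H3K27me3, 80.4% of untransduced and 29.6% of knockdown peaks were shared with a 50% overlap and 85.5% and 32.6% within 500 bp, and for H3K9me3 84.5% and 54.1% with a 50% overlap. With at least 50% of the MSX2 peak covered, the shares in untransduced and knockdown cells were 64.3% and 81.3% for ARID1A, 46.8% and 78.5% for SMARCA4, 49.3% and 62.2% for H3K27ac and 1.3% and 1.6% for H3K9me3. With a 50 kb window, where a gain needs 50 kb free of untransduced peaks and so counts other genes, the odds ratios at genes that rose on KD1 were 1.01 for ARID1A gained, 1.02 for SMARCA4 gained, 0.784 for SMARCA4 lost and 1.18 for H3K27ac gained. With genes matched on expression they were 1.81 for SMARCA4 lost, which lost its call, and 0.591 for H3K27ac lost and 2.64 for H3K27me3 lost, which became called.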

Other observations

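In this part all of the values were chosen after the data were seen, and none carries an explanation. Replicate 1 stood apart from replicates 2 and 3 in each group with 3 libraries. The chi-square over its degrees of freedom between replicates 2 and 3 was 6.37 in shGFP, 7.58 in KD1, 7.06 in SR and 37.0 in ST without doxycycline, and for the pairs with replicate 1 it was 20.5 to 27, 33.1 to 46.4, 20.9 to 27.5 and 94.9 to 180.4. In KD1 this showed in interferon genes. IFI6, an interferon-induced mitochondrial protein, stood at 8405 CPM in KD1 replicate 1 and 6035 CPM in the library labelled KD2, which also has replicate number 1, and at 2913 and 3720 CPM in KD1 replicates 2 and 3.

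Of the 920 genes that rose on KD1, 79 were lower in the library labelled KD2 and 2 were called lower there. Of the 410 that fell, 103 were higher and 8 were called higher. CGA, the gonadotropin alpha subunit, stood at 87130 ± 30080 CPM in ST cells without doxycycline (n = 3), 2493 ± 1565 CPM with doxycycline (n = 2) and 799.6 ± 456 CPM in SR cells (n = 3), beside 11870 ± 427 CPM in SR cells with KD1 (n = 3) in the other table, a level between SR and ST cells. MSX2 peaks also lay within 5 kb of 18.5% of the genes that rose in the library labelled KD2 against 8.8% of genes not called (odds ratio 2.35, Fisher's exact test, p = 5.65e-12), and of 5 of the 160 genes that fell there (3.1%, odds ratio 0.335, p = 0.00715). For fallen genes the odds ratio was 0.489 (p = 0.292) with a 1 kb and 0.795 (p = 0.192) with a 50 kb window, both by Fisher's exact test.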
